A study of Danio rerio with 2 samples.

How the data were processed

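RNA was measured in 2 sequencing libraries from zebrafish (Danio rerio) embryos of the crestin_1kb:EGFP line, in which a fragment of the crestin gene, a marker of the neural crest, drives the fluorescent protein EGFP. The embryos were raised to the stage given as 15 SS, dissociated and separated by fluorescence-activated cell sorting. One library was made from about 5500 EGFP-positive cells and the other from about 100000 EGFP-negative cells. Per the labels' protocols, RNA was extracted with Trizol and a carrier, ribosomal RNA was depleted, and libraries were made with a low-input kit and sequenced on an Illumina HiSeq instrument.

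The authors deposited 1 table of FPKM values (fragments mapped to a gene, scaled by its length and by the library's mapped fragments), with 1 row per gene symbol and 1 column per library. Its columns were matched to the libraries by the sample descriptions. Every column of values in it matched a sample. The submitters' processing notes name cutadapt, TopHat2 version 2.0.11, Cufflinks version 2.2.1 and the genome build Zv9. Their options, the gene annotation and the normalisation between libraries are not given in the sources used here. FPKM corrects for gene length and for library size, so the deposited values carry no total count and the sequencing depth of each library is unknown. Low values were searched for the steps that whole reads would leave. Among 712 genes above 0 and under 6 FPKM in both libraries, no bin of 0.02 on the log2 scale held more than 1.54% of the ratios, so no step could be recovered and no counting interval is given.

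The table has 14428 rows and gives symbols without coordinates, so no genome position is printed. Of these names, 11348 are current symbols in the reference gene tables and 2558 are older symbols there. A spreadsheet had turned 9 names into dates, and these rows were kept in the counts but not named. In 58 rows several symbols were joined, and each of these rows held a symbol that also has a row of its own. For such genes the estimate can be split between the rows, so they are treated as uncertain. The crestin gene and EGFP were not analysed here, so the planned check of the sort on its own marker was not made. Members of gene families with near-identical copies, such as the globin and histone genes, can share reads.

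With 1 library per group there is no replicate, no estimate of spread between samples and no test. Differences are therefore described by size. The log2 ratio of a gene was log2(FPKM + 1) in the EGFP-positive library minus log2(FPKM + 1) in the EGFP-negative library. The pseudocount of 1 FPKM understates the ratio of genes with low values. Genes were considered when they reached at least 1 FPKM in either library, and called higher or lower at a size of at least 2-fold on that scale. Folds written as a ratio of FPKM are the plain quotient of the 2 deposited values. An exact 0 can be a failed or lost estimate rather than an absent transcript, since genes used by every cell were also listed at 0, so no fold is given against a 0.

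Before the data were examined, 34 gene lists were fixed: regulators of the neural crest, its derivatives, other cell types of the embryo, signalling pathways, hox genes, and genes of growth, stress and metabolism. Those lists were written from general knowledge, and some genes stand on more than 1 list. In the patterns that select genes by symbol, the sign for alternatives had been stored as another character and was read as intended. For each list, the median log2 ratio was ranked among the medians of 10000 random lists of the same size. The random lists were drawn from 20 bins of equal size by mean log2 expression, without the list's own members. This percentile describes these 2 libraries and is not a p-value over replicates. The interval given with some medians is the order-statistic interval over the list's genes, at a level of 95%, and genes are not independent replicates.

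The rule for naming genes was also fixed in advance. It names sox10, foxd3, tfap2a and mitfa, the 15 genes with the highest and the 15 with the lowest log2 ratio among those at 5 FPKM or more in either library, any measured member of the neural crest and pigment lists, and up to 4 members of each other list in the direction of its median and 2 against it. Clone and locus names were passed over. Because those 30 extreme genes were nearly all listed at 0 in the other library, the 15 highest and 15 lowest among genes above 0 in both were added after the data had been seen.

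Both statistics were run on simulated data made from the real table. Over 9685 genes, of 200 random lists of 20 genes with no shift, 3.5% fell outside the 2.5th to 97.5th percentiles. The log2 ratios had been shuffled within the same 20 bins, so this share was largely set in advance. Shuffling removes dependence between related genes, so the share does not show how often real lists would be extreme by chance. Lists shifted by 0.5, 1 and 2 on the log2 scale fell above the 97.5th percentile in 26%, 72% and 100% of 50 draws each. In a second simulation, the EGFP-negative library was copied and 4-fold changes were placed on some of its 8951 genes above 0. No noise was added, so the recovered sizes show only the effect of the pseudocount. The median recovered log2 size, against a true 2, was 1.54 for genes from 1 up to 5 FPKM, 1.79 from 5 up to 20 FPKM and 1.96 from 20 FPKM upwards.

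The alternatives were pseudocounts of 0.1 and 5, no filter on low values or a minimum of 5 FPKM, 2 ways of rescaling the libraries, leaving out genes at 0 in either library, a 4-fold size threshold, unmatched random lists, and lists without shared members. A minimum of 20 FPKM was added after the data had been seen. Computations used Python 3.11.15 with numpy 2.4.6, pandas 2.3.3 and scipy 1.17.1, and figures were drawn with matplotlib 3.10.9.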

Results

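Gene expression was compared between EGFP-positive and EGFP-negative cells sorted from crestin_1kb:EGFP zebrafish embryos at 15 SS, to describe which genes mark the cells in which the crestin fragment is active. The neural crest is the migratory embryonic population that gives rise to pigment cells, peripheral neurons and glia, and part of the head skeleton. Each fraction was represented by 1 library, so no value has a replicate error and no difference was tested. Of the 14428 rows, 8439 were above 0 FPKM in the EGFP-positive library and 8951 in the EGFP-negative library. The median of the genes above 0 was 21.7 FPKM in the EGFP-positive and 19.9 FPKM in the EGFP-negative library. The most abundant transcript in both was rn7sk, a small nuclear RNA, which made up 13.9% of the summed FPKM in the EGFP-positive and 6.85% in the EGFP-negative library.

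Across the 9685 genes that reached at least 1 FPKM in either library, 2218 were at least 2-fold higher and 2571 at least 2-fold lower in the EGFP-positive library. These counts include 893 and 1343 genes that were listed at 0 in the other library. Among genes above 0 in both, 1325 were higher and 1228 lower. Across all 9685 genes, those at 0 in one library included, expression was correlated, with Pearson's r = 0.63 and Spearman's rho = 0.65, although genes are not independent replicates. The scatter of single genes was smallest among the most abundant. The SD of the log2 ratio was 1.27 over 901 genes with a geometric mean from 1 up to 5 FPKM, 1.35 over 2431 genes from 5 up to 20 FPKM, 0.85 over 1088 genes from 100 up to 1000 FPKM, and 0.55 over 114 genes from 1000 FPKM upwards.

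Regulators of the neural crest were higher in the EGFP-positive library. Of 27 measured members, 16 were at least 2-fold higher, 2 were lower and 9 lay between. Sox10, a transcription factor of the crest and of its pigment and glial derivatives, stood at 147 against 16.3 FPKM, a 9.01-fold ratio of FPKM. The forkhead factor foxd3 stood at 86.7 against 7.04 FPKM, a 12.3-fold ratio, and tfap2a at 188 against 44.6 FPKM, a 4.22-fold ratio. Ednrab, an endothelin receptor, was at 229.5 against 16.2 FPKM. The paired-box factors pax7a (74.2 against 4.63 FPKM), pax7b (89.4 against 15.6 FPKM) and pax3a (172 against 59.3 FPKM) were all higher, as was prdm1a (112 against 22.1 FPKM). The neuregulin receptor gene erbb3b was at 16.4 FPKM in the EGFP-positive library and 0.032 FPKM in the other.

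Twist1a was at 387 against 155 FPKM, zeb2a at 122 against 41.6 FPKM, msxb at 129 against 52.4 FPKM and id2a at 780.3 against 322 FPKM, each at least 2-fold higher. The snail family members snai2 (66.0 against 59.2 FPKM) and snai1b (152 against 109.6 FPKM), and tfap2c (118.5 against 92.4 FPKM), lay less than 2-fold apart. The 2 lower members were the endothelin receptor gene ednraa, at 70.25 FPKM in the EGFP-negative library and listed at 0 in the EGFP-positive one, and zeb2b, at 1.07 against 3.77 FPKM. The list's median log2 ratio was 1.28, with an interval over genes of 0.60 to 2.29, and it exceeded the medians of all 10000 matched random lists. The median was also 1.28 over the 24 members above 0 in both libraries. Kidney and hatching gland genes were higher in the same library, as given further on.

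**Figure D1:**
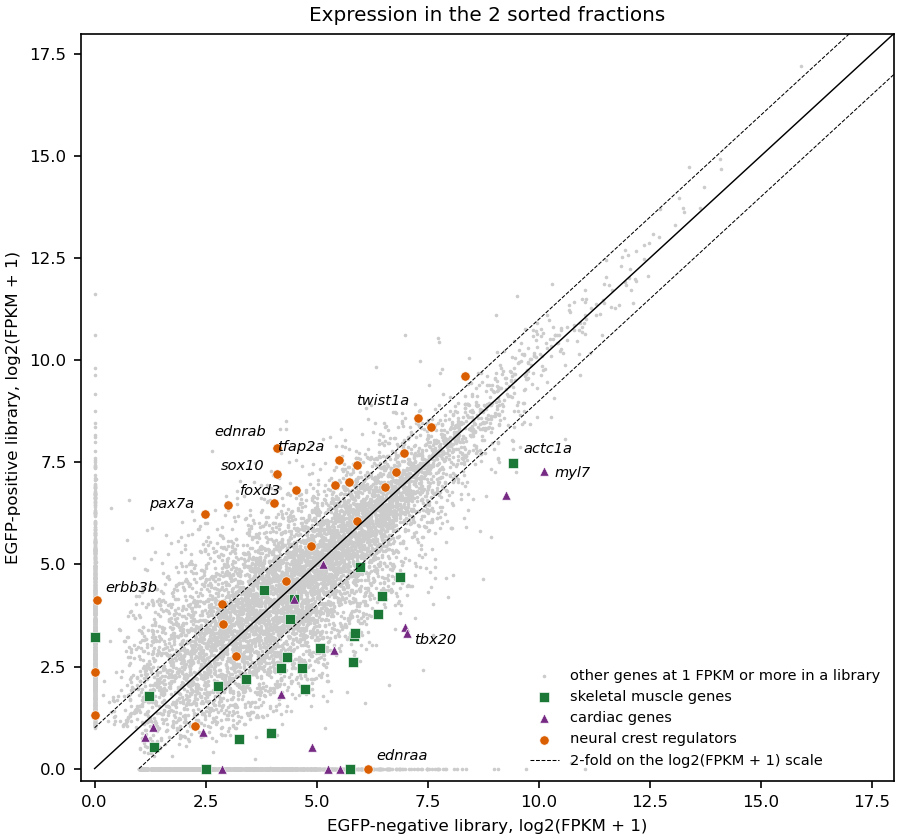
Expression of single genes in the EGFP-negative (horizontal) and EGFP-positive (vertical) library, both as log2(FPKM + 1). The solid line marks equal values and the dashed lines a 2-fold difference; most neural crest regulators (orange) lie above the lines, and most skeletal muscle (green) and cardiac genes (purple) below them, while points on either axis are genes listed at or near 0 in one library.

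Pigment cell genes showed no common direction at this stage. Only 9 of the 19 listed genes reached 1 FPKM, of which 3 were higher, 4 lower and 2 between. Mitfa, the master regulator of melanocytes, was at 1.295 FPKM in the EGFP-positive and 6.20 FPKM in the EGFP-negative library. Kita, a receptor of pigment precursors, was at 0.722 against 11.4 FPKM, and gch2, an enzyme of pteridine synthesis, at 25.4 against 59.1 FPKM. Trpm1b, a melanocyte channel gene, was higher, at 70.9 against 7.80 FPKM. The melanosome gene pmela (3.32 FPKM) and the iridophore kinase gene ltk (1.31 FPKM) were measured in the EGFP-positive library and listed at 0 in the other. Rab27a (54.1 FPKM) was listed at 0 in the EGFP-positive library. The median log2 ratio of -0.15 lay at the 48.7th percentile of random lists. Over the 6 members above 0 in both libraries the median was -0.67, at the 7.86th percentile. Genes of purine and pteridine synthesis had a median of 0.17, at the 73.3rd percentile, with gart at 195 against 79.4 FPKM and gch1 at 71.8 against 21.1 FPKM.

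Among genes of crest derivatives and migration, single members differed while the lists did not stand apart. Dlx2a, a factor of the cranial crest mesenchyme, was at 38.4 against 1.57 FPKM, while foxc1b was at 3.60 against 28.2 FPKM, and foxf2a, at 10.9 FPKM in the EGFP-negative library, was listed at 0 in the EGFP-positive one. That list held 7 higher and 8 lower members of 20, with a median of 0.12 at the 67.8th percentile. Without the members it shares with other lists, its median was -0.84 at the 1.57th percentile. Of 13 peripheral neuron and glia genes 6 were higher and 4 lower, with a median of 0.59 at the 88.2nd percentile. Neurog1, a neurogenic factor (40.9 FPKM), and pou4f1, a sensory neuron factor (16.2 FPKM), were listed at 0 in the EGFP-negative library. The glial gene mpz was at 7.23 against 0.0027 FPKM. Of 29 migration and adhesion genes 5 were higher, among them the cadherins cdh6 (152 against 50.3 FPKM) and cdh7 (68.9 against 17.8 FPKM), the guidance receptor robo1 (30.4 against 9.93 FPKM) and itgb1a (120.4 against 47.5 FPKM). Cdh11 (19.1 against 68.4 FPKM) and the protease mmp14a (2.62 against 11.8 FPKM) were among the 4 that were lower, and the list median was 0.03, at the 60.0th percentile.

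Most genes listed for muscle, heart, vessels and unsegmented mesoderm were lower in the EGFP-positive library. Of 25 skeletal muscle genes 18 were lower and 1 higher, with a median log2 ratio of -2.13. Myf5, a muscle determination factor, was at 5.12 against 55.2 FPKM and mylpfa, a fast myosin light chain, at 2.84 against 25.8 FPKM, while tnnt3b, at 8.29 FPKM, was listed at 0 in the EGFP-negative library. Presomitic mesoderm genes had 16 of 23 members lower and none higher, with a median of -2.13. Ripply1 (44.6 FPKM) and her12 (53.2 FPKM) were listed at 0 in the EGFP-positive library. The other 7 members lay less than 2-fold apart. Outside the naming rule, these included msgn1 (27.7 against 29.4 FPKM), ntla (29.7 against 25.0 FPKM) and eve1 (74.7 against 42.3 FPKM), so the list was not lower throughout. Of 15 cardiac genes 11 were lower and none higher, with a median of -2.56, including the ventricular myosin vmhc (0.43 against 28.6 FPKM) and tnni1b (8.91 against 131 FPKM). Outside the naming rule, the cardiac genes myl7 (156 against 1107 FPKM) and cmlc1 (103 against 612 FPKM) were also lower. Both stayed well above 0 in the EGFP-positive library. Endothelial genes had 12 of 19 members lower and none higher, with a median of -1.96. The vascular cadherin cdh5 stood at 2.70 against 50.3 FPKM and etv2, an early factor of the vessel lineage, at 55.5 against 407 FPKM. Each of these 4 medians lay below those of all 10000 matched random lists.

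Blood, notochord and ionocyte genes were also lower, by smaller or less secure amounts. Of 25 blood cell genes 10 were lower and 1 higher, with a median of -0.76 at the 0.30th percentile. Spi1b, a factor of white blood cells, was at 7.57 against 71.6 FPKM. The other 14 blood cell genes lay less than 2-fold apart on the log2(FPKM + 1) scale. Outside the naming rule, these included the globin gene hbae1 (1157 against 2287 FPKM), gata1a (11.3 against 14.2 FPKM) and lyz (105.6 against 53.8 FPKM). The notochord and floor plate list had 9 lower members of 17 and a median of -1.55, at the 0.46th percentile. The median was -0.35, at the 12.1th percentile, when the 7 members listed at 0 in one library were left out, among them cav1 (14.35 FPKM) and ntn1b (14.5 FPKM), both at 0 in the EGFP-positive library. The ionocyte factors foxi3b (51.8 FPKM) and foxi3a (8.86 FPKM) were listed at 0 in the EGFP-positive library, as were slc9a3.2 (15.9 FPKM) and atp1b1b (6.12 FPKM). Of the 6 measured ionocyte genes 5 were lower, and all 5 were listed at 0 there. One ionocyte gene, atp6v1aa, was above 0 in both, at 37.1 against 17.02 FPKM, so the list's median of -3.07, at the 0.39th percentile, rests on values listed at 0.

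Neural tube genes were mixed, with 10 higher and 17 lower of 42 measured and a median of -0.50 at the 3.89th percentile. Over the 31 members above 0 in both libraries the list lay at the 1.76th percentile. Dbx1b, an interneuron progenitor factor (117 FPKM), and sox21a (40.3 FPKM) were listed at 0 in the EGFP-positive library, while neurog1 and olig4 (34.1 FPKM) were listed at 0 in the EGFP-negative one. Of 22 epidermis and periderm genes 7 were higher and 1 lower, with a median of 0.13 at the 68.4th percentile. Epcam, an epithelial adhesion gene, was at 97.4 against 22.3 FPKM, and icn (40.2 FPKM) was listed at 0 in the EGFP-negative library. Placode and otic genes had 5 higher and 7 lower members of 20, with a median of 0.13 at the 67.9th percentile. Endoderm genes had 4 higher and 6 lower of 13, with a median of -0.61 at the 23.4th percentile that became 0.28 without genes at 0. Of 5 measured yolk layer lipoprotein genes 2 were higher and 1 lower, with a median of 0.19 at the 66.4th percentile.

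Kidney and hatching gland genes were higher in the EGFP-positive library. Of 12 kidney genes 7 were higher and 3 lower, with a median of 1.40, an interval over genes of -1.59 to 2.21, at the 99.8th percentile. Hnf1ba, a factor of the kidney tubule, was at 34.5 against 0.86 FPKM, the salt cotransporter gene slc12a3 at 40.6 against 4.59 FPKM and slc4a2a, an anion exchanger gene, at 86.7 against 17.9 FPKM. Cxcl12a (6.39 against 55.7 FPKM) and podxl (18.6 against 110.0 FPKM) were lower. Of 7 hatching gland genes 4 were higher and 1 lower, with a median of 1.40, an interval of -1.05 to 2.90, at the 99.9th percentile. The hatching enzyme genes he1a and he1b, close relatives that can share reads, were at 1004 against 159.9 FPKM and 134 against 31.6 FPKM. The lower hatching gland gene was klf4b, at 42.9 against 90.2 FPKM, and xbp1, outside the naming rule, was at 209 against 208 FPKM. In all, 8 lists lay below the 2.5th and 6 above the 97.5th percentile, where 1.7 of the 34 would fall outside by chance if genes were independent.

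**Figure D2:**
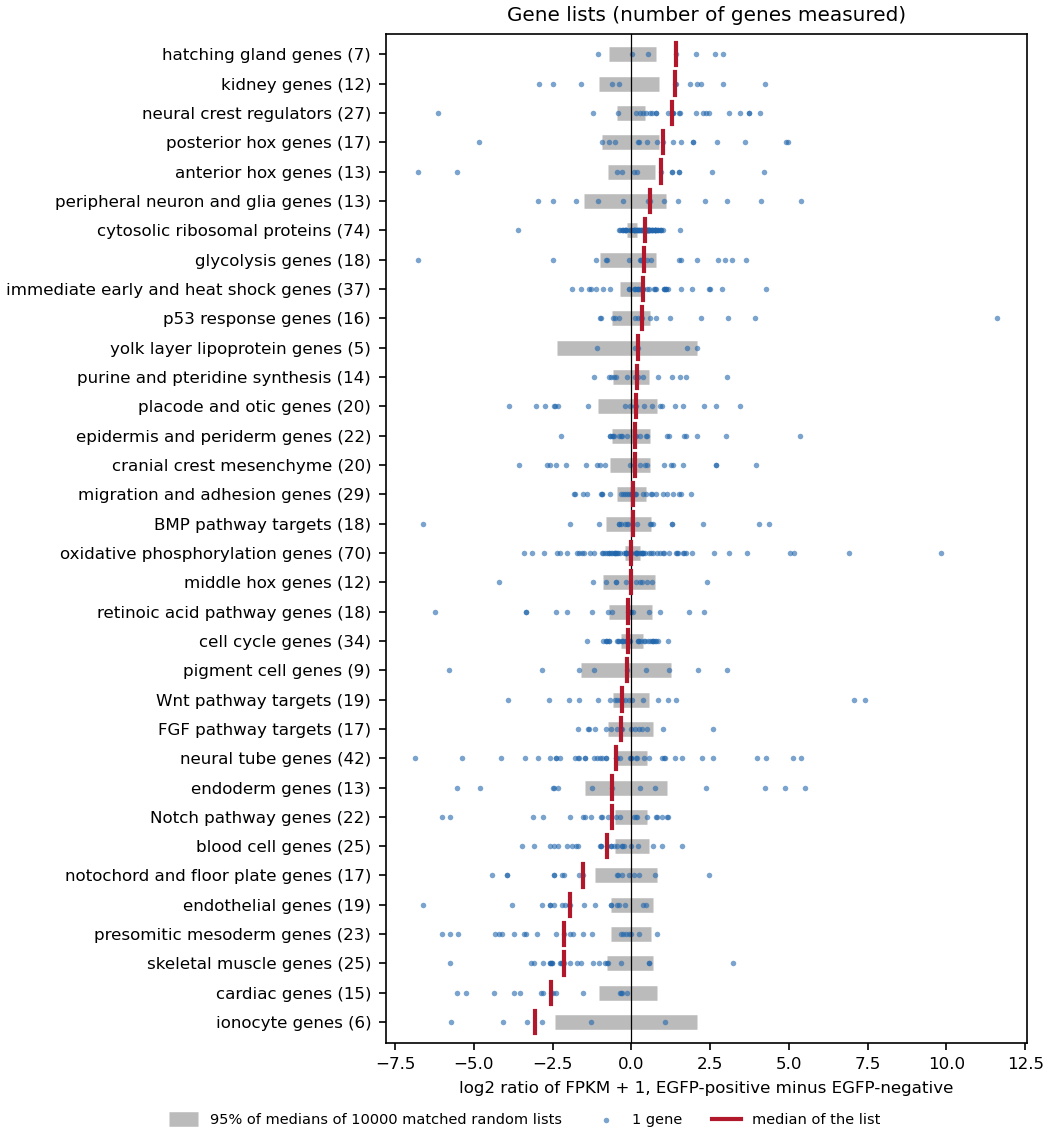
Log2 ratios of the members of each fixed gene list, EGFP-positive minus EGFP-negative, on log2(FPKM + 1). Each blue point is 1 gene, the red bar the list's median and the grey band the range of 95% of the medians of matched random lists; the hatching gland, kidney and neural crest lists lie to the right of their bands, and the muscle, presomitic, endothelial and cardiac lists to the left.

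The hox genes, which record position along the body axis, were grouped by paralogue number, and differences between the groups were not tested. Of 13 anterior genes, from groups 1 to 4, 6 were higher and 2 were lower, with a median of 0.93 at the 99.2nd percentile. Hoxb2a was at 368 against 18.8 FPKM and hoxc4a at 79.7 against 12.7 FPKM, while hoxc1a (109.4 FPKM) and hoxb4a (45.6 FPKM) were listed at 0 in the EGFP-positive library. With a minimum of 20 FPKM, chosen after seeing the data, the anterior list lay at the 68.3rd percentile, over 11 genes. The 12 middle genes, from groups 5 to 8, had 1 higher and 2 lower members and a median of -0.02 at the 52.7th percentile. Of 17 posterior genes, from groups 9 to 13, 9 were higher and 1 lower, with a median of 1.00 at the 98.9th percentile. Over the 13 members above 0 in both libraries the median was 0.82, at the 97.4th percentile. Hoxa9a was at 117 against 16.9 FPKM. Hoxd13a (30.3 FPKM) and hoxa11a (28.8 FPKM) were listed at 0 in the EGFP-negative library, and hoxd12a (27.5 FPKM) in the EGFP-positive one.

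**Figure D3:**
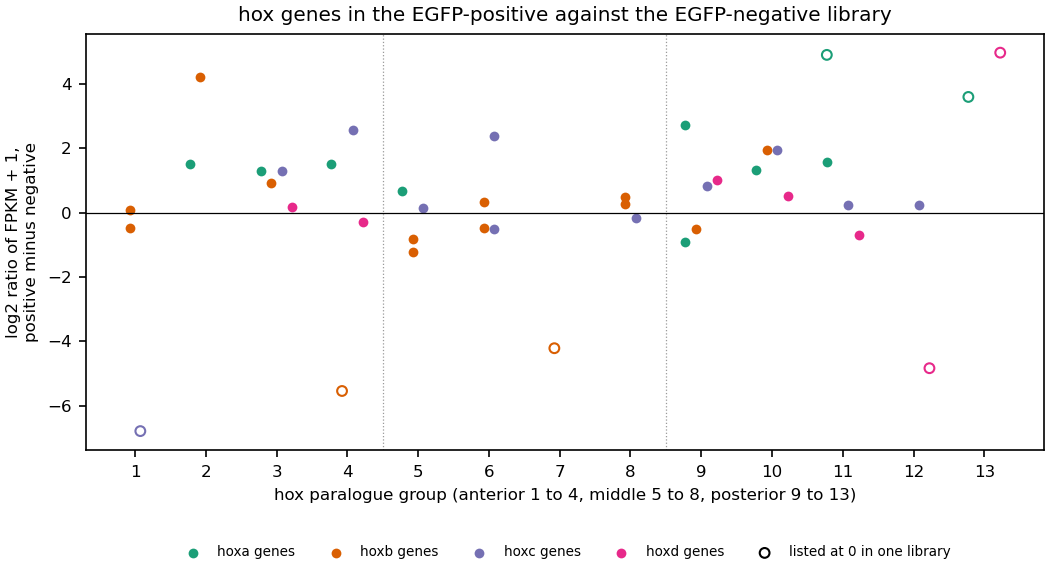
Log2 ratio of each measured hox gene, EGFP-positive minus EGFP-negative on log2(FPKM + 1), by paralogue group. Filled points are genes above 0 in both libraries and open points genes listed at 0 in one; hoxb2a, hoxc4a and hoxa9a stand highest among the filled points.

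Among signalling pathways, Notch genes had the lowest list median. Notch pathway genes had 2 higher and 8 lower of 22, with a median of -0.61 at the 0.98th percentile; this list shares her12 and other genes with the presomitic list, and lay at the 10.9th percentile without shared members and at the 4.99th without genes at 0. Hey1 was at 1.12 against 17.6 FPKM. Wnt pathway targets had 4 higher and 5 lower of 19 and a median of -0.31. The Wnt inhibitor gene dkk1b (171 FPKM) was listed at 0 in the EGFP-negative library, and nkd2a was at 135 against 0.020 FPKM. FGF targets had 2 higher and 4 lower of 17, with dusp4 at 126 against 20.2 FPKM and etv4 at 13.2 against 31.0 FPKM. BMP targets had 5 higher and 3 lower of 18, and retinoic acid pathway genes had 2 higher and 6 lower of 18. Aldh1a2, the enzyme that makes retinoic acid in the somites, was at 1.89 against 28.2 FPKM, and rdh10a at 5.21 against 62.3 FPKM. The medians of the Wnt, FGF, BMP and retinoic acid lists were -0.31, -0.33, 0.03 and -0.10, between the 13.7th and the 60.8th percentiles.

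Cell cycle genes mostly lay close together in the 2 libraries. Of 34 measured, 32 lay less than 2-fold apart, with cdca8 (346 against 155 FPKM) higher and cenpe (26.6 against 72.0 FPKM) lower, and the median was -0.11 at the 23.7th percentile. Cytosolic ribosomal protein genes were slightly higher as a group, with a median of 0.43 above all random lists, although 71 of 74 lay less than 2-fold apart. The 114 genes with a geometric mean of 1000 FPKM or more, several ribosomal ones among them, had a median of 0.24. A shift of abundant transcripts as a whole was not separated from this. Immediate early and heat shock genes had 12 higher and 5 lower of 37, with a median of 0.36 at the 97.2nd percentile. Atf3, a stress-induced factor, was at 238 against 42.0 FPKM and klf2a at 9.68 against 0.471 FPKM, while the co-chaperone dnajb1a was at 22.4 against 85.5 FPKM. P53 response genes had 5 higher and 1 lower of 16 and a median of 0.32 at the 85.9th percentile, with the stress gene sesn2 at 47.0 against 4.68 FPKM. Glycolysis genes had 7 higher and 3 lower of 18, with a median of 0.41 at the 86.9th percentile. Ldha was at 79.9 against 5.56 FPKM and the glucose transporter gene slc2a1a at 69.8 against 9.64 FPKM, while tpi1b (109.7 FPKM) was listed at 0 in the EGFP-positive library. Oxidative phosphorylation genes had 16 higher and 12 lower of 70 and a median of -0.01 at the 37.2nd percentile.

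The largest single differences were mostly genes listed at 0 in one library. The 15 highest genes were all at 0 in the EGFP-negative library, led by the apoptosis gene pmaip1 (3142 FPKM), the ATP synthase subunit gene atp5l (902 FPKM), the mitochondrial ribosome gene mrpl36 (792 FPKM) and ccdc58 (574 FPKM). Of the 15 lowest, 14 were at 0 in the EGFP-positive library, led by the small nuclear RNA rnu11 (844 FPKM), nfyc (541 FPKM) and usp22 (513 FPKM). The other was the histone gene h2afz, at 0.11 against 1711 FPKM. A joined row of h2afva and h2afz held 1566 against 125 FPKM, and the 2 rows summed to 1566 and 1836 FPKM, so h2afz is uncertain. Among genes above 0 in both libraries, the axon guidance receptor gene unc5c (217 against 5.25 FPKM), the phosphatase gene ptprdb (58.4 against 1.45 FPKM) and cdkal1 (319 against 17.02 FPKM) stood among the highest. The vitamin D receptor gene vdra (4.33 against 168 FPKM), the somite factors tbx24 (8.74 against 196 FPKM) and tbx6 (0.98 against 35.4 FPKM), and the splicing regulator rbfox1l (24.0 against 427 FPKM) stood among the lowest.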

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

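With 1 library per group, leaving out a replicate was not possible, no result could be tested and the depth is unknown. No paired analysis was possible because each group held 1 library. The minimum of 20 FPKM was chosen after seeing the data. The numbers of genes at least 2-fold higher in the EGFP-positive library and of genes at least 2-fold lower in the EGFP-positive library, 2218 and 2571, became 1325 and 1228 with genes at 0 in either library left out, 1114 and 1398 at a 4-fold size, and 1103 and 1163 with a minimum of 20 FPKM, each because fewer genes could pass. Under the other alternatives they ranged from 1561 to 2337 higher and from 1731 to 2692 lower. The rescalings shifted log2 ratios by 0.0061 and 0.020 and changed the sign of no list median, so they test little. The neural crest median ranged from 0.88 with a pseudocount of 5 to 1.53 without shared members and stayed above the 97.5th percentile under every alternative run, as did the kidney, hatching gland and ribosomal protein lists. The muscle, presomitic, endothelial, cardiac and blood lists stayed below the 2.5th percentile under every alternative run, and the pigment list stayed between these bounds. The ionocyte median of -3.07 reversed to 1.08 without genes at 0, where 1 gene was left. Of the 34 lists, the number whose percentile crossed 2.5 or 97.5 was 5 without genes at 0, 4 with a minimum of 20 FPKM, 3 without shared members, 2 with a minimum of 5 FPKM, 1 with a pseudocount of 5 and 1 against unmatched lists. Notochord and Notch genes were among them under several of these, and the cause was not tested.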

Other observations

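All tests and the added gene lists in this part were chosen after the values had been seen. Amino acid and one-carbon metabolism genes that belong to the integrated stress response, a shared reaction to amino acid shortage and protein folding stress, included several with higher values in the EGFP-positive library. Asns, asparagine synthetase, was at 54.4 against 15.9 FPKM, shmt2 at 67.0 against 20.7 FPKM, the transporter subunit gene slc3a2b at 68.5 against 9.51 FPKM and chac1 at 27.7 against 8.80 FPKM. Mthfd2 (91.1 FPKM) and ddit3 (10.8 FPKM) were listed at 0 in the EGFP-negative library. The aminoacyl-tRNA synthetase genes aars (284 against 279 FPKM) and tars (55.1 against 52.2 FPKM) and the serine synthesis genes psat1 (131 against 145.5 FPKM) and psph (30.6 against 33.1 FPKM) lay less than 2-fold apart. Among the lower genes, cars was at 6.95 against 17.6 FPKM, and the proline synthesis genes aldh18a1 (3.09 FPKM) and pycr1 (3.14 FPKM) and the receptor gene vldlr (2.92 FPKM) were listed at 0 in the EGFP-positive library.

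A candidate explanation for these values is an integrated stress response in the sorted EGFP-positive cells. Over 29 such genes 8 were higher and 4 lower, with atf3 and sesn2, given above, among the higher ones. The median log2 ratio was 0.44, at the 96.85th percentile of random lists, short of the 97.5th. Because the list was chosen after the values had been seen, its percentile cannot decide, and this explanation stays open. For a heat shock type of handling stress, none of the 6 measured heat shock genes was at least 2-fold higher and 2 were lower in the EGFP-positive library, where hsp70 (0.385 FPKM in the other library) and hsp70l (0.213 FPKM in the other) were listed at 0. The median of the 6 was -0.49 with an interval of -1.88 to 0.37, against 0.55 (0.21 to 1.08) for 31 immediate early genes. With 6 genes the interval spans their whole range, so its overlap with the other interval decides nothing. This second candidate explanation therefore stays open. A difference between crest and other cells in these genes was not tested, since no unsorted library was analysed here.

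Kidney and hatching gland genes were higher in a fraction sorted for crest cells, with 11 of 19 members at least 2-fold higher, 4 lower and a joint median log2 ratio of 1.40, whose interval over genes was -0.61 to 2.21. Random carry-over of EGFP-negative cells alone would give a log2 ratio of at most 0. The interval includes such values and these lists were singled out because their values were high, so random carry-over stays open. Values listed at 0 do not account for the median, since the 17 members above 0 in both libraries had a median of 1.38. Activity of the crestin fragment in such cells, autofluorescent cells within the gate, and expression of these genes in the crest itself stay open and untested.

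Many genes were listed at 0 in one library and well above 0 in the other. Absence of the transcript from a cell population is unlikely for genes used by every cell, yet 11 of 125 such genes at 20 FPKM or more in one library, 8.8% (lower bound of the exact 95% interval 4.48%), were listed at 0 in the other, against 561 of 5448, 10.3%, over all genes at that level. Reads assigned to joined rows touched 11 of the 2236 rows concerned, 0.49%, and so leave nearly all of them unexplained. From genes at 1 up to 5 FPKM to genes at 100 up to 1000 FPKM in the other library, the share at 0 was lower, 33.3% against 3.35% in the EGFP-positive and 24.6% against 3.02% in the EGFP-negative library, where 1.55% were still at 0 from 1000 FPKM upwards. Few sampled molecules could give the first trend but not readily zeros opposite abundant genes, and this stays open because the lengths of the transcripts, which set how many fragments a given FPKM stands for, were not used here.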
